A study of Mus musculus with 9 samples.

How the data were processed

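Total RNA from 6 mouse alveolar rhabdomyosarcomas and 3 wild-type skeletal muscles was extracted with Trizol and RNAeasy and labelled with biotin for Affymetrix arrays, per the labels' protocols. The deposited values are linear MAS5 signal intensities, 1 per probe set and array, and MAS5 is named without a version in the submitters' processing notes. MAS5 subtracts a local background and mismatch probes and can multiply each array to a common target. The scaling target, filters and scan dates are not given in the sources used here, and detection calls were not used here. Low signals can therefore be background, and folds against them are uncertain.

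The deposited intensities were looked at before any test. On 7 of the 9 arrays the mean signal, trimmed by 2% at each end, was 500 within 1 unit, but it was 294.3 on muscle 1 and 140.9 on muscle 3. The design fixed before the data were examined had taken all arrays to be scaled by MAS5 and planned no second normalization. Because 2 of the 3 muscles were not on the common scale, every array was multiplied to the median trimmed mean, with factors of 1.6995 for muscle 1 and 3.5493 for muscle 3. This departs from the written design. It was decided after the values had been seen and before any test was run, and the comparison without rescaling is given as an alternative. No columns were duplicates, and every per-sample column was used.

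Of 22690 probe sets, 64 control probe sets were left out. Of the rest, 20380 had 1 gene symbol in the platform annotation, 691 had several and 1555 had none, and only those with 1 symbol were named. Gene identifiers of 20364 probe sets were found in a table of mouse genes of the GRCm38.p6 assembly, used for names only, and 0 symbols needed an update. No coordinates are given, since the array annotation names no genome build. The 12393 genes were each represented by the probe set with the highest mean log2 value over all 9 arrays. The group labels did not enter this choice, but 6 of the 9 arrays are tumours, so it can favour probe sets that are bright in tumours. Of these genes 4956 had several probe sets. Among the called genes 3, Gid4, Tpm1 and Tpm3, had probe sets called in both directions, and Gid4 and Tpm1 are named because of that and were chosen after their values were seen. Some probe sets bind transcripts of related genes, such as the sarcomeric myosins, so values of close paralogs are less certain.

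Tests ran on log2(signal + 16) with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with an intensity trend over all 9 arrays and no covariates. P-values were adjusted by the Benjamini-Hochberg method and genes were called at an adjusted p under 0.05. Differences are tumour minus muscle, and folds are on the same offset scale. Gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, which asks whether a list's genes move one way on balance. The 42 lists were written before the data were examined and hold 868 symbols, of which 770 were on the array. They cover muscle structure and metabolism, myogenic and tumour-associated genes, cell division, growth pathways and markers of other cell types. Summaries and permutation tests were computed with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

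The genes named were set by a rule written before the data were examined. It took the 10 largest rises and the 10 largest falls among called genes whose groups did not overlap and whose brighter group lay above the median of all values. It also took 20 genes fixed in advance, of which 19 were on the array, up to 3 called members per described list in the main direction and up to 2 in the other, and control probe sets. Class II genes were fixed with their test beforehand, while single muscle genes named with the tumour 1 values were chosen after values were seen. The fit was tested on simulated data for this comparison, with 200 of 12393 genes changed. It called 2% of genes changed 2-fold and 39% of those changed 4-fold, with 0 false calls, and the slope of estimated on true log2 differences was 0.987. The simulation drew genes independently, with 1 spread per gene for both groups, and changed fewer genes than the 2200 called in the data. Its shares and its 0 false calls hold for that setting, in which small differences often went uncalled.

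Alternatives planned in advance were quantile normalization, median centring, offsets of 1 and 64, leaving out genes of below-median brightness, the mean of a gene's probe sets, each probe set on its own (for a gene, the medians of its differences and adjusted p), eBayes without the trend, a weight per group, an exact rank-sum test, a block for replicate numbers and leaving out each array. Added after the data had been seen were the comparison without rescaling and one without tumours 1 and 4.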

Results

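Total RNA was profiled from 6 mouse alveolar rhabdomyosarcomas and 3 samples of wild-type skeletal muscle, each on 1 Affymetrix array. Alveolar rhabdomyosarcoma is a soft-tissue cancer that expresses skeletal muscle genes, and in patients many of these tumours carry a fusion of PAX3 or PAX7 with FOXO1. The comparison asks how gene expression in the mouse tumours differs from that of skeletal muscle. The labels used here give neither the genotype of the tumours nor the muscles sampled, nor whether the samples came from separate animals. Each array gave a MAS5 signal for 22690 probe sets, a linear brightness in arbitrary units, and 12393 genes could be tested. The number of arrays limits the precision, and p-values measure the spread between these samples, which they treat as independent.

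The 3 muscles resembled each other more than the tumours did. Across genes, the mean Pearson correlation of log2 signals was 0.931 between muscles (3 pairs), 0.829 between tumours (15 pairs, from 0.655 to 0.925) and 0.729 between a tumour and a muscle (18 pairs). Genes are not independent replicates, so these values describe the arrays and were not tested. Tumour 1 stood farthest from the rest, with a mean correlation of 0.737 with the other tumours and 0.664 with the muscles. The 100 brightest probe sets held 20.1% of its signal, against 9.4% to 14.6% on the other arrays. The hybridisation control cre gave a signal of 36984 on tumour 1 and 28015 on tumour 4, against 6026 to 13440 elsewhere after rescaling. The poly-A control dap, which is added to the RNA, lay between 124 and 1640 on the tumour arrays and between 3080 and 5781 on the muscle arrays after rescaling; as deposited, the muscles lay between 1629 and 4718, and muscle 3 below tumour 5. The ratio of the 3' to the 5' Gapdh probe set, a sign of RNA quality, was 57.17 on muscle 2 and 33.0 on muscle 3 but 1.68 on muscle 1, and 1.93 to 9.39 on the tumours. The same ratio of Actb was also lowest on muscle 1, but muscles 2 and 3 did not lie above the tumours. It was 1.87, 4.06 and 4.35 on muscles 1 to 3 and 3.35 to 6.78 on the tumours.

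Adult muscle genes were lower in the tumours, and genes of cell division, myeloid cells and antigen presentation were higher. Of 12393 genes, 2200 differed between tumour and muscle at an adjusted p under 0.05 (limma, Benjamini-Hochberg), 1073 of them higher and 1127 lower in tumours. Of these, 2187 differed at least 2-fold on the scale of log2(signal + 16), on which folds of dim genes are understated. Among all genes, 2681 (21.6%) had tumour and muscle signals that did not overlap, where chance gives 2.38%, and 1986 of these were called. On the offset scale the largest rises among bright genes were Pmaip1 (Noxa, a pro-apoptotic BH3-only protein), Lgals3 (galectin-3) and Lst1, at 73.2-fold, 68.4-fold and 53.4-fold. Their order depends on the offset, since the muscle means of Pmaip1 and Lst1 were 7 and 20: the log2 differences of Pmaip1, Lgals3 and Lst1 were 7.74, 6.38 and 6.5 with an offset of 1 and 4.61, 5.46 and 4.56 with one of 64. Lgals3 had a signal of 6266 ± 2837 in tumours (SD, n = 6) and 70 ± 19 in muscles (SD, n = 3), with an adjusted p of 1.7e-06. They were followed by Cks2 (33.4-fold, a subunit that binds cyclin-dependent kinases), Ms4a6d (33.1-fold), Il13ra1 (31.2-fold, a receptor chain for interleukin-13), Stc1 (26.9-fold, the secreted glycoprotein stanniocalcin), Ccl5 (24.7-fold, a chemokine), Tk1 (24.1-fold, thymidine kinase) and Cdc20 (23.7-fold, an activator of the anaphase-promoting complex). The deepest falls were those of Ckmt2 (177-fold, the mitochondrial creatine kinase of striated muscle), Pgam2 (174-fold, the muscle phosphoglycerate mutase) and Myh4 (136-fold, a fast myosin heavy chain). Their order depends on tumour 1, whose signals were 201, 771 and 12817, against at most 108, 87 and 335 in the other tumours. The Stc1 call was lost as the median over its 2 probe sets (adjusted p = 0.082), and that of Myh4 on tumours 1 to 3 and the 3 muscles alone (0.052). Ckmt2 had a signal of 89 ± 60 in tumours (SD, n = 6) and 16992 ± 4083 in muscles (SD, n = 3), with an adjusted p of 9.4e-07. Muscle 1 and muscle 3 were deposited on another scale than the other 7 arrays and were rescaled. Without that step 2742 genes were called, 2373 higher and 369 lower, so that 86.5% were higher instead of 48.8%, and the median difference of all genes was 0.79 instead of 0.10 (log2). The count was 1267 without muscle 2 and 1110 without muscle 3, and 2881 without tumours 1 and 4.

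Genes of the adult contractile apparatus were lower in the tumours. Of 16 measured fast-fibre contractile genes 15 were lower and 1 did not pass (16 lower when adjusted over the list alone), with a median log2 difference of -4.83 (camera adjusted p = 6.9e-15; adjusted p = 0.094 with an estimated correlation). Pvalb, the calcium buffer parvalbumin, had a signal of 777 ± 1490 in tumours (SD, n = 6) and 23329 ± 3341 in muscles (SD, n = 3), and differed by -6.41 ± 0.92 (log2 ± SE). Pvalb and the enzyme gene Pgam2 stood on the fast-fibre list without being contractile genes themselves. Of its 16 genes 4 were shared with other lists, Pvalb with calcium handling and Pgam2 with glycolysis. Counts of these lists are therefore not independent. Of 15 genes of the Z-disc, titin and M-band 12 were lower (15 adjusted over the list alone), with a median of -4.12 (adjusted p = 2.3e-13; adjusted p = 0.094 with an estimated correlation). Among them were Myom2 of the M-band at -6.26 ± 0.74, and Myot (myotilin) and Cmya5 at -6.09 ± 0.73 and -6.09 ± 0.66. Actn3, the fast-fibre alpha-actinin, differed by -6.40 ± 1.08, Sh3bgr by -6.80 ± 0.74 and the transcription factor gene Sox6 by -6.29 ± 0.47. Of 15 genes of calcium handling and excitation-contraction coupling 11 were lower (12 adjusted over the list alone), with a median of -3.88 (adjusted p = 2.4e-10; adjusted p = 0.13 with an estimated correlation). They included Cacna1s, the calcium channel subunit of the T-tubule, at -5.29 ± 0.63. Of 18 genes of the dystrophin complex and laminin receptors 10 were lower (11 adjusted over the list alone), with a median of -1.55 (adjusted p = 6.5e-05; adjusted p = 0.11 with an estimated correlation), such as Cav3 (caveolin-3) at -3.81 ± 0.69 and Sgca (alpha-sarcoglycan) at -3.39 ± 0.51. Of the 18, 5 were lower without the rescaling of 2 muscle arrays, and 6 to 10 when 1 array was left out. Slow-fibre genes changed less evenly. Of 10, 4 were lower and 1 higher (5 and 1 adjusted over the list alone), with a median of -1.62 (adjusted p = 0.0053; adjusted p = 0.27 with an estimated correlation and 0.056 with fry). Leaving out 1 array gave 2 to 5 lower. Myh7, the slow myosin heavy chain, differed by -3.90 ± 0.73 and Myl3 by -3.21 ± 0.48. The higher member was Tpm3, at 1.86 ± 0.36, but of its 5 probe sets 2 were called in each direction, so its direction is uncertain.

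Adult muscle signals were not equally low in every tumour. For 36 genes of the contractile, calcium and glycogen lists with a mean muscle signal over 5000, the median signal was 17.23% of the muscle mean in tumour 1, 3.25% in tumour 2, 3.76% in tumour 6 and 1.38%, 1.14% and 0.92% in tumours 3, 4 and 5. Tumour 1 had the highest signal of the 6 tumours for 29 of the 36. Its Myh4 signal was 12817, against 16 to 335 in the other tumours and 20311 to 31509 in the muscles.

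**Figure D1:**
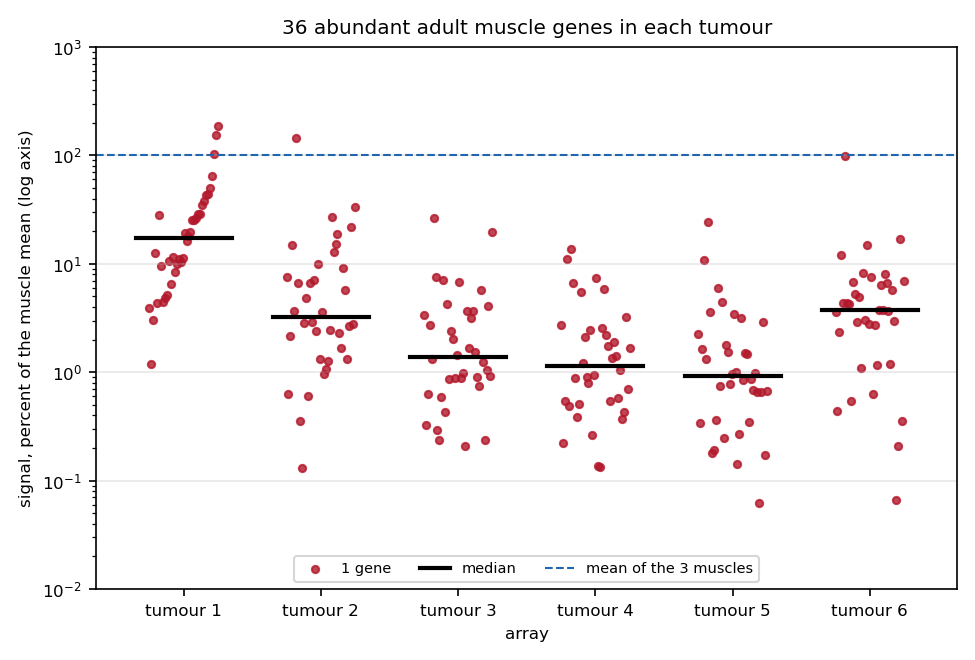
Signal of 36 abundant adult muscle genes in each tumour, as a percent of the mean of the 3 muscles (vertical axis, logarithmic); each point is 1 gene, the black bars are medians and the dashed line is the muscle mean. The median is 17.23% in tumour 1 and between 0.92% and 3.76% in the other tumours.

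Genes of oxidative and energy metabolism were also lower. Of 34 measured genes of oxidative phosphorylation 26 were lower (27 adjusted over the list alone, and 14 to 27 when 1 array was left out) and none was called higher, with a median log2 difference of -1.73 (camera adjusted p = 4e-16; adjusted p = 0.0007 with an estimated correlation). Cox7a1, the muscle and heart isoform of a cytochrome c oxidase subunit, differed by -4.76 ± 0.81. Of 16 TCA cycle genes 14 were lower (15 adjusted over the list alone), with a median of -2.08 (adjusted p = 6.3e-14; adjusted p = 0.0099 with an estimated correlation). They included the dehydrogenase genes Ogdh at -3.10 ± 0.32 and Idh3a at -3.11 ± 0.39, and Dlat of the pyruvate dehydrogenase complex at -3.19 ± 0.33. Of 23 genes of fatty acid oxidation 20 were lower (21 adjusted over the list alone), with a median of -2.06 (adjusted p = 4e-16; adjusted p = 0.0007 with an estimated correlation). Pdk4, a kinase that inhibits pyruvate dehydrogenase, had a signal of 185 ± 93 in tumours (SD, n = 6) and 5043 ± 206 in muscles (SD, n = 3). Of 18 genes on the list of glycogen and creatine metabolism 13 were lower (13 lower and 1 higher adjusted over the list alone), with a median of -3.92. The camera adjusted p was 5.3e-13, and 0.013 with an estimated correlation. Among the 13 were Pygm, the muscle glycogen phosphorylase, at -5.84 ± 0.93 and Adssl1, a purine nucleotide gene also placed on this list, at -5.94 ± 0.49. Without the rescaling 2 of the 18 were higher and 11 lower. Glycolysis genes went both ways, with 7 of 19 lower and 5 higher (8 and 6 adjusted over the list alone). This balance turned to 4 lower and 6 higher without the rescaling of 2 muscle arrays, and leaving out 1 array gave 5 to 9 lower and 3 to 6 higher. The muscle forms Pgam2 and Eno3 and the insulin-regulated glucose transporter gene Slc2a4 were lower, at -7.44 ± 0.74, -3.97 ± 0.42 and -3.88 ± 0.45. The general forms Pgam1 and Slc2a1 were higher, at 2.30 ± 0.32 and 3.34 ± 0.71, though Slc2a1 was not called on tumours 1 to 3 and the 3 muscles alone (adjusted p = 0.067). The call of the glycolysis list as lower (median -0.76, adjusted p = 0.043; adjusted p = 0.54 with an estimated correlation) was lost with quantile normalization and with median centring, at adjusted p of 0.054 and 0.06 in a range of 0.016 to 0.54 over 23 alternatives. It was also lost without tumour 2 (0.056), tumour 3 (0.15) or muscle 3 (0.054). Without the rescaling of 2 muscle arrays its median was 0.10, above 0, while camera still placed it lower than other genes (0.017). Without that step, 6 genes of oxidative phosphorylation, 6 of the TCA cycle and 7 of fatty acid oxidation were called lower, while camera still called the 3 lists.

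Among myogenic regulators and genes linked to the human tumour, most did not pass the test. Of 20 genes chosen in advance 19 were measured, and 4 were higher, 1 lower and 14 not called; Trp53 was not analysed here. Ncam1, a cell adhesion molecule of developing muscle, had a signal of 2319 ± 839 in tumours (SD, n = 6) and 95 ± 42 in muscles (SD, n = 3), a 20.9-fold rise with an adjusted p of 1.3e-05. Its 6 probe sets differed in the same direction and 3 were called, but as their median the call was lost (0.086, in a range of 3.2e-09 to 0.086 apart from the rank-sum test). Cdk4, a kinase of the G1 phase, rose 4.54-fold (adjusted p = 0.003), and Myf6, the myogenic factor most abundant in adult muscle, fell 15.8-fold (adjusted p = 0.00014). The embryonic myosin heavy chain gene Myh3 had a signal of 1456 ± 1718 in tumours (SD, n = 6), from 166 to 4681, and 125 ± 37 in muscles (SD, n = 3), with an adjusted p of 0.039. Foxo1 had a signal of 2353 ± 1658 in tumours (SD, n = 6) and 649 ± 244 in muscles (SD, n = 3), a 3.05-fold difference with an adjusted p of 0.046. Its 4 probe sets differed in the same direction and 1 was called. Both calls were lost under quantile normalization, at adjusted p of 0.06 for Myh3 and 0.053 for Foxo1, and under median centring (0.088 and 0.08), in ranges of 0.00046 to 0.15 and 0.0022 to 0.36 over 23 alternatives. Myh3 was also not called without tumour 3 (0.061), tumour 6 (0.072), muscle 1 (0.08), muscle 2 (0.12) or muscle 3 (0.15), and Foxo1 without tumour 4 (0.072), tumour 5 (0.091), tumour 6 (0.07), muscle 1 (0.18), muscle 2 (0.072) or muscle 3 (0.15). Myh3 was also not called with an offset of 64 (0.051), nor Foxo1 with the mean of its probe sets (0.15), as their median (0.36), without the trend (0.064), without tumours 1 and 4 (0.066) or on tumours 1 to 3 and the 3 muscles alone (0.29). Pax3 had a signal of 75 ± 64 in tumours (SD, n = 6) and 186 ± 136 in muscles (SD, n = 3), and Pax7 one of 115 ± 74 and 177 ± 106, with adjusted p of 0.19 and 0.61. Which part of each transcript these probe sets read was not examined. The values of Pax3, Pax7 and Foxo1 therefore do not tell whether a fusion transcript was present. Myod1 and Myog, the myogenic determination factor and myogenin, differed by 0.34 ± 0.45 and 0.36 ± 0.48 (log2 ± SE), less than their error. Some genes varied widely from tumour to tumour without passing the test. The receptor gene Fgfr4 ranged from 37 to 7851 in tumours (adjusted p = 0.47), Pdgfra from 48 to 3308 (adjusted p = 0.53) and Myf5 from 81 to 2155 (adjusted p = 0.33). Igf2, Met, Mycn, Cdkn2a, Ccnd2, Chrng and Myh8 differed by 0.75 ± 0.53, 1.45 ± 0.58, -0.14 ± 0.41, 1.19 ± 0.45, 0.33 ± 0.62, 1.71 ± 0.69 and -1.01 ± 0.56. Pdgfra was called higher without tumour 1 (adjusted p = 0.0068, in a range of 0.0012 to 0.96), Chrng without tumour 4 (0.042, in a range of 0.014 to 0.66) and Cdkn2a without tumour 2 (0.015, the lowest of a range up to 0.42) or with quantile normalization (0.041). Without the rescaling of 2 muscle arrays Met, Myf5, Igf2, Fgfr4, Chrng and Cdkn2a were called higher, at adjusted p of 0.017, 0.038, 0.041, 0.049, 0.014 and 0.021; the ranges of the first 4 reach 0.34, 0.73, 0.73 and 0.88. With a weight per group Met, Chrng and Cdkn2a were called higher (0.042, 0.035 and 0.032).

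**Figure D2:**
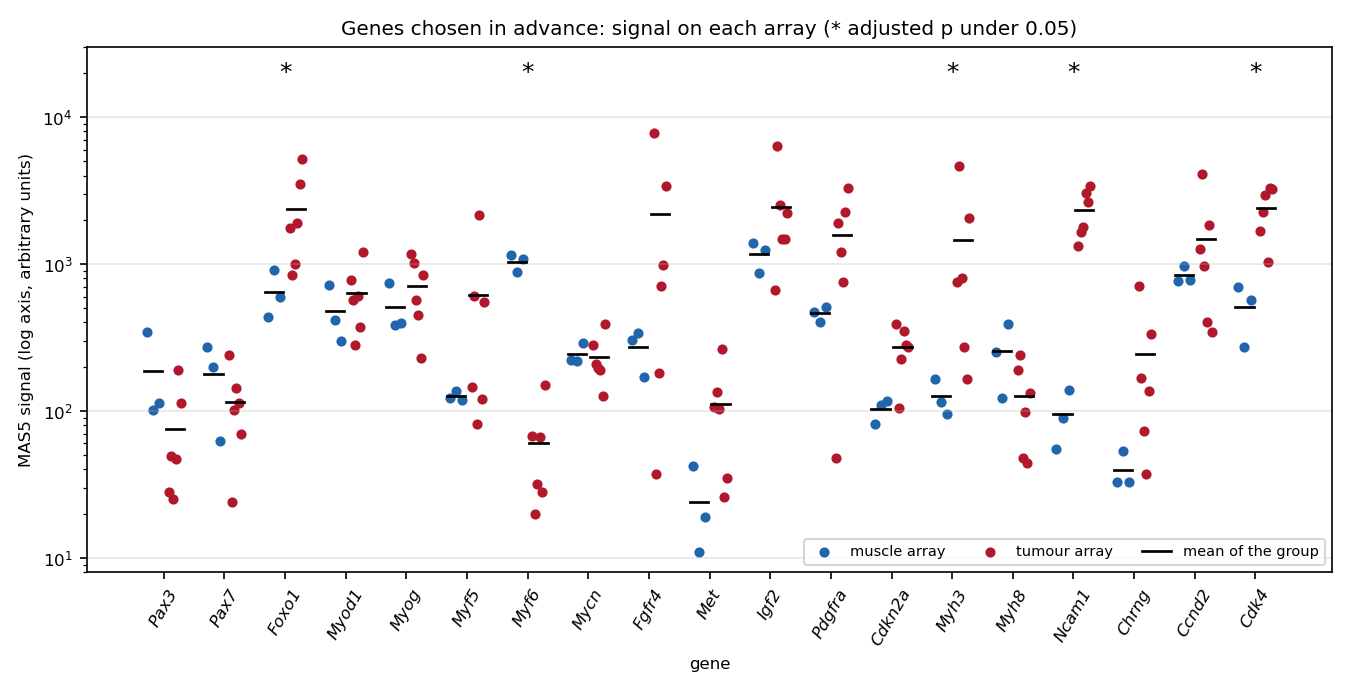
MAS5 signal of the 19 measured genes chosen in advance (vertical axis, logarithmic, arbitrary units); each point is 1 array, blue for muscle and red for tumour, black bars are group means and a star marks an adjusted p under 0.05. Ncam1, Cdk4, Myh3 and Foxo1 were called higher and Myf6 lower, and the other 14 were not called.

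None of the 3 lists of these genes was called as shifted in a single direction. The mixed form of fry, which asks whether members change in either direction, gave low adjusted p. These were 3.3e-10 for myogenic regulators, 2e-09 for the embryonic list and 6.3e-06 for the PAX-FOXO1 list. Low values of that form were common among the 42 lists. Of 22 myogenic regulators 6 were lower and 2 higher (6 and 2 adjusted over the list alone), with a median log2 difference of 0.0 (camera adjusted p = 0.15). This turned to 5 higher and 2 lower, with a median of 0.76, without the rescaling of 2 muscle arrays. The lower ones included Mef2c at -3.54 ± 0.72 and Meox2 at -2.37 ± 0.42, and the higher ones were Id2 at 1.75 ± 0.46 and Id1 at 1.60 ± 0.51, which encode inhibitors of myogenic factors. The calls of Id2 and Id1 were lost without any 1 of the muscles, at adjusted p of 0.061 to 0.074 and 0.1 to 0.19, and that of Id1 also without tumour 3 (0.069), tumour 4 (0.084), tumour 5 (0.057) or tumour 6 (0.079). Id1 was also not called with an offset of 64 (0.055) or without tumours 1 and 4 (0.081), neither was called on tumours 1 to 3 and the 3 muscles alone (0.21 for Id2, 0.28 for Id1), and Meox2 was not without the rescaling (0.058). Of 17 genes of the embryonic and perinatal sarcomere and of myoblast fusion 2 were higher and 3 lower (5 and 3 adjusted over the list alone), with a median of 0.76 (adjusted p = 0.41, and 0.043 on tumours 1 to 3 and the 3 muscles alone, in a range of 0.037 to 0.87 over 23 alternatives). Without the rescaling 9 were higher and 3 lower, with a median of 1.46, and leaving out 1 array gave 1 to 4 higher and 2 to 3 lower. The lower ones included the cardiac actin gene Actc1 at -3.34 ± 0.69. Of 25 genes associated with human PAX-FOXO1 tumours 2 were higher, Cdk4 and Skp2 (4.39 ± 0.44, a subunit of a ubiquitin ligase of the cell cycle), and none was lower (2 adjusted over the list alone). Without tumour 1, 4 were higher and 1 lower, and without the rescaling 7 were higher. The median of that list was 0.46 (adjusted p = 0.12, and 0.039 with the mean of all probe sets of a gene, in a range of 0.039 to 0.42 over 23 alternatives).

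Genes of cell division were higher in the tumours. Of 32 measured genes of the G2 and M phases 28 were higher (29 adjusted over the list alone) and none was called lower, with a median log2 difference of 2.63 (camera adjusted p = 2.1e-20; adjusted p = 0.027 with an estimated correlation). Ube2c, a ubiquitin-conjugating enzyme of mitosis, was 18.4-fold higher (adjusted p = 0.00014), and Kif2c, a mitotic kinesin, differed by 4.32 ± 0.50 (log2 ± SE), although 2 of the 4 probe sets of Kif2c went the other way and the call was lost as their median (adjusted p = 0.46). Of 31 genes of the G1/S transition and DNA replication 23 were higher (26 adjusted over the list alone, and 12 to 25 when 1 array was left out), with a median of 1.78 (adjusted p = 1.1e-13; adjusted p = 0.054 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, had a signal of 3342 ± 1341 in tumours (SD, n = 6) and 289 ± 134 in muscles (SD, n = 3), and Mcm6, of the replicative helicase, one of 1169 ± 466 and 89 ± 55. Of 17 genes of DNA repair and checkpoints 4 were higher (6 adjusted over the list alone), with a median of 0.80 (adjusted p = 0.0044; adjusted p = 0.054 with an estimated correlation), led by the checkpoint kinase gene Chek1 at 3.03 ± 0.39 (not called as the median over its 4 probe sets, adjusted p = 0.14). Of the 17, 9 were higher without the rescaling of 2 muscle arrays, and 2 to 7 when 1 array was left out. Of 10 Myc family and oncofetal genes 3 were higher (4 adjusted over the list alone), with a median of 0.96 (adjusted p = 0.0063; adjusted p = 0.063 with an estimated correlation). Without the rescaling 5 of the 10 were higher, with a median of 1.47. Hmga2, an oncofetal chromatin protein, differed by 4.52 ± 0.43 and Myc by 2.01 ± 0.43. The third was Igf2bp3, at 1.79 ± 0.51, of whose 4 probe sets only 1 was higher. Igf2bp3 was not called with the mean of its probe sets (0.78), as their median (0.75), without tumour 4 (0.05), tumour 5 (0.055), muscle 2 (0.078), muscle 3 (0.17) or tumours 1 and 4 together (0.056). On tumours 1 to 3 and the 3 muscles alone Igf2bp3 (0.12), Myc (0.073) and Cdkn2b (0.062) were not called. In the p53 pathway list, which was not called (median 0.23, adjusted p = 0.99), 2 of 19 genes were higher and 1 lower, with the same counts adjusted over the list alone. The higher ones were Pmaip1 and Cdkn2b, an inhibitor of Cdk4, at 6.19 ± 0.68 and 2.26 ± 0.49, and the lower one was Ccng1 at -3.97 ± 0.38. Without the rescaling 4 were higher and 1 lower.

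Markers of myeloid cells and genes of antigen presentation were higher in the tumours. Of 21 macrophage and myeloid markers 18 were higher (19 adjusted over the list alone) and none was called lower, with a median log2 difference of 2.64 (camera adjusted p = 6.3e-14; adjusted p = 0.02 with an estimated correlation). The complement gene C1qa had a signal of 1548 ± 748 in tumours (SD, n = 6) and 43 ± 12 in muscles (SD, n = 3). Ctss, the protease cathepsin S, differed by 3.97 ± 0.42 and the Fc receptor gene Fcgr3 by 3.69 ± 0.48. Of 20 genes of antigen presentation and the interferon response 17 were higher (19 adjusted over the list alone) and none was called lower, with a median of 2.47 (adjusted p = 4.8e-13; adjusted p = 0.011 with an estimated correlation). They included Bst2 at 4.14 ± 0.48, the immunoproteasome gene Psmb8 at 3.32 ± 0.48 and Oasl2 at 3.31 ± 0.47. Neither lymphocyte nor granulocyte lists were called. Of 17 markers of T, NK and B cells 1, Gzmb, was higher (1 adjusted over the list alone; median 0.15, adjusted p = 0.75), and of 14 neutrophil and mast cell markers 1, S100a8, was higher (0 adjusted over the list alone; median 0.15, adjusted p = 0.47; 3 higher without the rescaling of 2 muscle arrays). Gzmb was not called without muscle 2 (adjusted p = 0.074) or muscle 3 (0.083). S100a8 was not called without any 1 of the muscles (0.092 to 0.11) or without tumour 4 (0.059), tumour 5 (0.07) or tumour 6 (0.064). S100a8 was also not called with quantile normalization (0.05), median centring (0.052) or an offset of 64 (0.052), and neither was called on tumours 1 to 3 and the 3 muscles alone (0.14 for Gzmb, 0.2 for S100a8). None of 5 red blood cell markers was called, over all genes or over the list alone (median -0.17, adjusted p = 0.76).

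Adipocyte markers were lower, and of the vessel markers 5 of 19 endothelial and 5 of 12 pericyte genes were. Of 12 adipocyte markers 9 were lower (11 adjusted over the list alone), with a median log2 difference of -3.22 (camera adjusted p = 4.7e-11; adjusted p = 0.013 with an estimated correlation). Adipoq, the fat cell hormone adiponectin, had a signal of 22 ± 13 in tumours (SD, n = 6) and 2447 ± 724 in muscles (SD, n = 3), and Cidea, a lipid droplet protein, differed by -3.85 ± 0.38. Of 19 endothelial markers 5 were lower (6 adjusted over the list alone), with a median of -0.90 (adjusted p = 0.00024; adjusted p = 0.26 with an estimated correlation). They included Aqp1 at -2.12 ± 0.46 and Fabp4, which fat cells also express, at -3.35 ± 0.56. Of the 19, 3 to 8 were lower when 1 array was left out, and without the rescaling of 2 muscle arrays 1 was lower and 1 higher, and Aqp1 was not called (0.097). Of 12 pericyte and smooth muscle markers 5 were lower (5 adjusted over the list alone), with a median of -0.64 (adjusted p = 0.0017; adjusted p = 0.13 with an estimated correlation), led by Rgs5 at -3.09 ± 0.38. Leaving out genes of below-median brightness ended that call (adjusted p = 0.063, in a range of 0.0006 to 0.13 over 23 alternatives). Its median was 0.11, above 0, without the rescaling of 2 muscle arrays, while camera still placed it lower than other genes (0.00096), and 2 of the 12 were lower. Leaving out 1 array gave 1 to 5 lower. Among the 5 was Des, at -2.85 ± 0.85, a call lost in 12 alternatives besides the rank-sum test. Its signal was 4036 in tumour 1 against 91 to 371 in the other tumours, a pattern also seen in adult muscle genes. The count of pericyte markers may therefore not reflect pericytes alone. Of 27 genes of the extracellular matrix and fibroblasts 2 were higher and 3 lower (2 and 3 adjusted over the list alone), with a median of 0.13 and a camera direction of lower (adjusted p = 0.99). Timp1, an inhibitor of matrix proteases, was higher at 4.50 ± 0.44 and Dpt (dermatopontin) lower at -2.32 ± 0.48, a call lost without the rescaling (0.062) and on tumours 1 to 3 and the 3 muscles alone (0.055). When 1 array was left out, 1 to 5 were higher and 1 to 4 lower, and without the rescaling 7 were higher and 1 lower. Of 10 basement membrane genes only Col18a1 was called, at 2.05 ± 0.54 (1 higher and 2 lower adjusted over the list alone; median -0.28, adjusted p = 0.53). Without the rescaling 3 were higher, with a median of 0.53, and without tumour 1, 1 was higher and 2 lower. Of 18 markers of Schwann cells and nerve only Mbp was called, at -2.04 ± 0.58 (none adjusted over the list alone; median 0.12, adjusted p = 0.76). Col18a1 was not called without any 1 of the muscles (0.062 to 0.079), nor Mbp without muscle 1 (0.16) or muscle 2 (0.08). Col18a1 was also not called with median centring (0.075), nor Mbp without the rescaling (0.16), and neither was on tumours 1 to 3 and the 3 muscles alone (0.057 and 0.16).

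**Figure D3:**
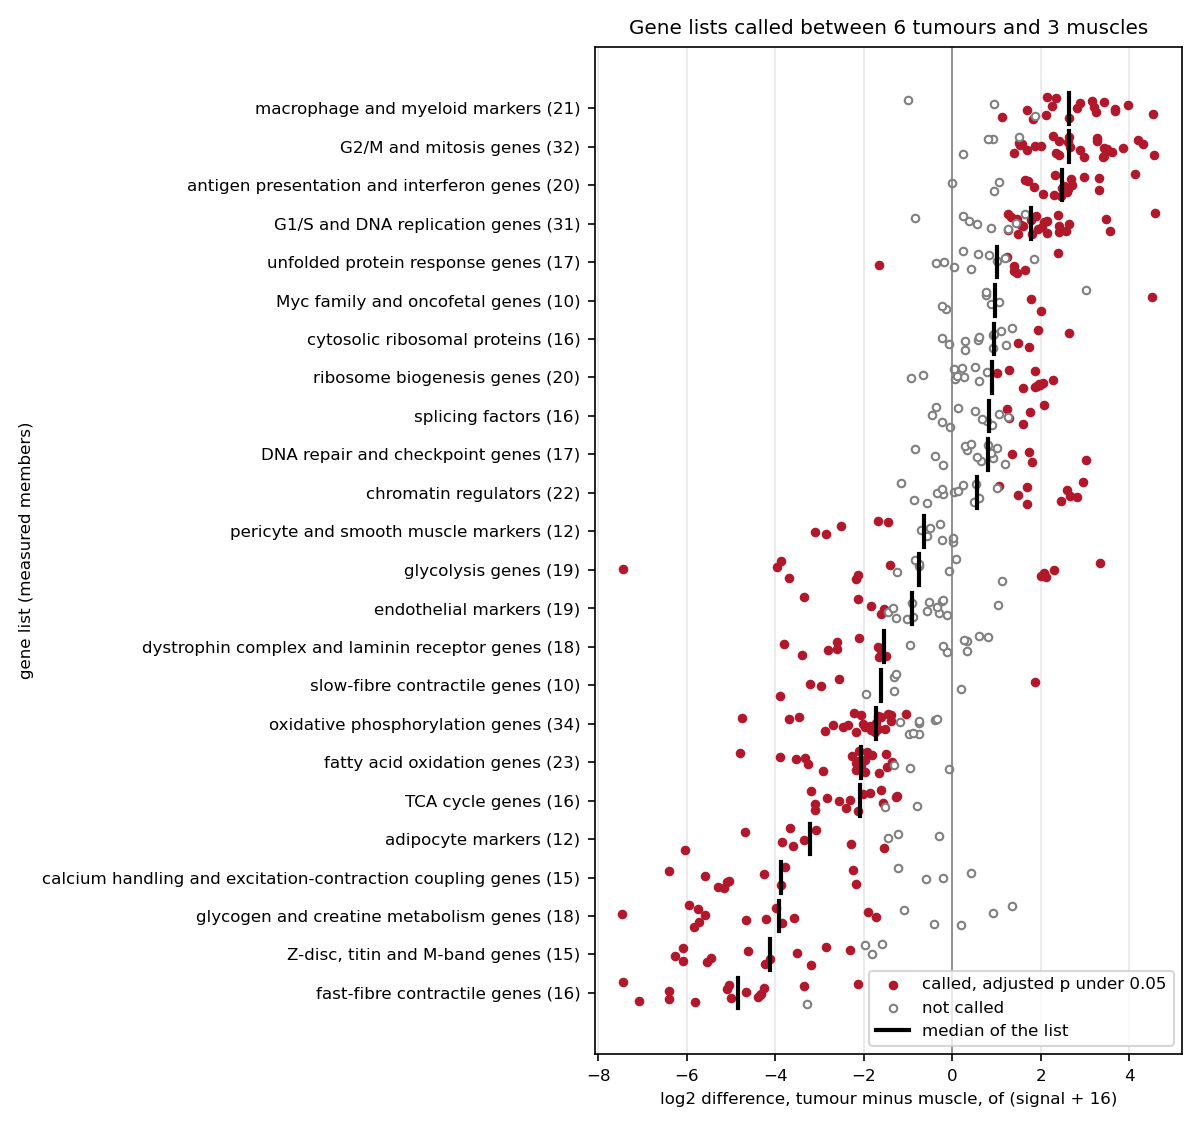
Differences of the measured members of the 24 gene lists called between 6 tumours and 3 muscles, as log2 of (signal + 16), tumour minus muscle (horizontal axis); each point is 1 gene, filled where it was called at an adjusted p under 0.05, and black bars are list medians. Medians run from -4.83 for fast-fibre contractile genes to 2.64 for macrophage and myeloid markers.

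In all, 24 of 42 lists were called by camera with its preset correlation of 0.01, 11 higher and 13 lower. With the correlation estimated for each list 8 calls held. These were G2 and M phase, oxidative phosphorylation, TCA cycle, fatty acid oxidation, glycogen and creatine, adipocyte, myeloid and antigen presentation genes. Muscles 2 and 3 had a higher Gapdh 3' to 5' ratio than any tumour array. Muscle 1 (1.68) lay below every tumour (1.93 to 9.39), so this ratio did not separate all muscles from all tumours. RNA quality is still not excluded as a factor, since no comparison left out muscles 2 and 3 together. After rescaling, every muscle array had higher dap than every tumour array, so dap moved with each of the gene groups above. As deposited, the dap of muscle 3 (1629) lay below that of tumour 5 (1640), but muscle 3 was then on another scale than the tumours. The Actb ratio did not separate the groups either (1.87 to 4.35 on the muscles and 3.35 to 6.78 on the tumours). Without tumours 1 and 4, 25 lists were called.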

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

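Of the tests in this part, only the count over other splits of the arrays and the relation of class II genes to myeloid markers were planned before the results were seen; all the others were chosen afterwards. For tumour 1, the tests of mixed-in muscle and of a steeper scale replaced earlier versions whose values had been seen, and both versions led to the same reading.

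The 6 tumours were checked for a single array far from the others in 81 sets of values, the largest rises and falls, the genes fixed in advance and the mean log2 value of each list. There were 6 such cases, where chance gives about 4. In tumour 1, Pgam2 and Sh3bgr were high, with gaps to the next tumour of 0.669 and 0.634 of the whole range, Pdgfra was low (0.629) and the calcium handling list was high (0.686). The antigen presentation list was high in tumour 5 (0.651) and the list of receptor tyrosine kinases and ligands was low in tumour 2 (0.635). Among 2246 probe sets without a single gene name, 202 were higher and 101 lower in tumours.

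The first pattern is the number of called genes. Of the 84 splits of the 9 arrays into 6 and 3, only 1, the real one, called as many as 2200 genes, and the highest other split called 7. That share, 1.2%, is the smallest this test can give, so chance is unlikely but not excluded. Every other split mixed tumours and muscles on at least 1 side, which widens the spread there and makes low counts likely. The outlying hybridisation controls of tumours 1 and 4 do not account for the number of calls, since 2058 of the called genes were also called, in the same direction, without these arrays. Separate handling of tumour and muscle RNA stays open. After rescaling, the lowest dap signal of a muscle was 1.88 times the highest of a tumour. Another poly-A control, thr, then lay between 775 and 1927 on the muscles and between 16 and 507 on the tumours. As deposited the dap ratio was 0.99, but muscle 3 was then on another scale than the tumours. On the common scale these controls followed the groups, so a difference in preparation cannot be told apart from tissue. Tumour against muscle, the difference the design names, stays open beside it.

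The second pattern is the adult muscle signal of tumour 1: if muscle like the 3 samples had been mixed in, the excess of tumour 1 over the other tumours should be about the same share of the way to the muscle mean for all 36 abundant genes. Its quartiles were 4.6% and 29.3%, a ratio of 6.31 (bootstrap 95% interval over genes 3.44 to 12.21, and 5.64 after quantile normalization, 2.59 to 10.79), with 0.8% for Ckmt2 and 192.6% for Myh1, which argues against it. The interval resamples genes measured on 1 array, which are not independent, so it does not measure uncertainty between samples. The reading rests on the spread between genes. An exchange with a muscle array is also argued against, since tumour 1 correlated better with the other tumours than with the muscles by 0.073 (SD of its correlations with tumours 0.048) and no muscle lay nearer to the tumours. A steeper brightness scale does not account for it, because tumour 1 stayed the highest tumour for 28 of the 36 genes after quantile normalization. Muscle of another fibre type in the sample, or muscle differentiation in that tumour, may give such a pattern, and neither was tested.

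The third pattern is the rise of myeloid and antigen presentation genes. A loss of muscle fibre RNA alone would raise markers of every other cell type alike. The median of the myeloid list lay 3.55 above that of the endothelial list (log2), and the latter was below 0. Medians of the other cell marker lists ran from -3.22 for adipocytes to 0.15 for T, NK and B cells. The T, NK and B cell list had mean log2 values of 6.49 to 7.57 on the arrays, below the median of all signals (8.15). Signals that low may be background and could hide a rise, so such lists cannot decide this. For the endothelial and adipocyte lists, which were brighter in muscle, the rise was not alike. The permutation p of 4e-05 for the first difference adds no independent support. It shuffles list members measured on the same 9 arrays, and both lists had already been called, in opposite directions. More myeloid cells in the tumours is a candidate explanation, and a change of expression within cells stays open. If class II genes came from those cells, their mean over Cd74, H2-Aa, H2-Ab1 and H2-Eb1 might follow the myeloid list from tumour to tumour. Pearson's r was 0.757 (exact one-sided permutation p = 0.083, adjusted 0.166 over 2 relations, n = 6) and Spearman's rho 0.486 (exact p = 0.178), and r was -0.072 without the 2 tumours farthest from the median, so no relation was shown.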

How the results depend on the processing

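The comparison without rescaling and the one without tumours 1 and 4 were chosen after the data had been seen, and the rest were planned. No alternative turned camera's direction of a called list, which is relative to other genes, but without rescaling the medians of the glycolysis and pericyte lists were 0.10 and 0.11, above 0. Apart from the rank-sum test, 67 of 130 called named genes and 8 of 24 called lists kept their call and direction in every alternative, and 68 and 8 did when left-out arrays are not counted. With the correlation estimated, 8 lists were called instead of 24. The exact rank-sum test called 0 genes after adjustment, since its smallest p with 6 and 3 arrays is 0.0238, which 2681 genes reached; 3415 lay below 0.05 unadjusted, against 3608 with limma. Tested one by one, 3488 probe sets were called, 1784 higher, 1704 lower and 3475 at least 2-fold, because more features were tested. Without rescaling, 2373 genes were higher and 369 lower, and 1440 of the main calls were shared. Leaving out 1 array gave 1110 to 2769 called genes, 503 to 1421 of them higher and 607 to 1348 lower, and 1110 to 2668 at least 2-fold. The lowest values came without muscle 3, and 1267 genes, 595 higher and 672 lower, were called without muscle 2. The mean correlation between muscles was 0.915 with an offset of 1. Without genes of below-median brightness it was 0.429 between tumour and muscle and 0.705 between tumours, while muscle pairs stayed at 0.92; the cause was not tested. The 3 muscles and 6 tumours limit the precision, and no signal over background could be computed without detection calls.

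Tumours 1 to 3 and muscles 1 to 3 share replicate numbers. Deviations of same-numbered arrays from their group means correlated at 0.228, 0.177 and -0.018, and tumour 3 correlated best with muscle 2 (0.036), so the numbers were not taken to pair samples. With the number as a replicate block, 1467 genes were called, 641 higher and 826 lower, and without it, on the same 6 arrays, 1089, 454 higher and 635 lower, all 1089 at least 2-fold; fewer samples entered both. The extracellular matrix list was then called higher, with medians of 0.34 and 0.34 (adjusted p = 0.031 with the block and 0.043 without). With the block 30 lists were called and without it 28. Gained in both were the embryonic (median 0.77, adjusted p = 0.037 and 0.043), serine and one-carbon (0.40, 0.032 and 0.038) and cholesterol (0.83, 0.04 and 0.043) lists, all higher. Egr1 was not called with the block (adjusted p = 0.053). With the block alone the lists of myogenic regulators (-0.24, 0.045) and red blood cells (-1.01, 0.04) were called lower. The cause of these changes was not tested. Tpm3 turned to -0.19 with the mean of its probe sets and Igf2bp3 to -0.08 as the median of its probe sets, since these disagree.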

Other observations

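Of the tests in this part, the relation between mitotic and contractile genes was planned before the results were seen; the gene lists were fixed in advance.

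At its preset correlation camera called 5 lists of ribosome, splicing, chromatin and unfolded protein response genes higher, and none of the 5 with an estimated correlation. Of 20 ribosome biogenesis genes 10 were higher (10 adjusted over the list alone), with a median log2 difference of 0.90 (camera adjusted p = 0.00079; adjusted p = 0.14 with an estimated correlation), led by Gar1 at 2.28 ± 0.44 (SE), a protein of small nucleolar particles. Of 16 cytosolic ribosomal proteins 4 were higher (5 adjusted over the list alone), with a median of 0.94 (adjusted p = 0.0014; adjusted p = 0.22 with an estimated correlation), such as Rps19 at 2.65 ± 0.41. Of 16 splicing factors 5 were higher (7 adjusted over the list alone), with a median of 0.84 (adjusted p = 0.0059; adjusted p = 0.22 with an estimated correlation), and 9 were higher without tumour 1. Without the rescaling of 2 muscle arrays 9 ribosomal protein, 10 splicing and 10 unfolded protein response genes were higher. Leaving out 1 array gave 2 to 5, 1 to 9 and 1 to 8, and 4 to 10 for ribosome biogenesis. Of 22 chromatin regulators 9 were higher (9 higher and 1 lower adjusted over the list alone), with a median of 0.56 (adjusted p = 0.0045; adjusted p = 0.094 with an estimated correlation). Among them were Hmgb2 at 2.95 ± 0.46, Uhrf1, which helps maintain DNA methylation, at 2.83 ± 0.47 (not called as the median over its 2 probe sets, adjusted p = 0.18), and the helicase gene Hells at 2.67 ± 0.45. Of 17 genes of the unfolded protein response 6 were higher and 1 lower (9 and 1 adjusted over the list alone), with a median of 1.02 (adjusted p = 0.0063; adjusted p = 0.062 with an estimated correlation). Asns, asparagine synthetase, differed by 2.38 ± 0.42 and the lower gene, Dnajb9, by -1.65 ± 0.52; with median centring 3 were higher and none lower. Dnajb9 was not called without tumour 3 (0.063), tumour 4 (0.076), tumour 5 (0.072), muscle 2 (0.21) or muscle 3 (0.13), nor with quantile normalization (0.054), median centring (0.089), no trend (0.057), no rescaling (0.32), without tumours 1 and 4 (0.055) or on tumours 1 to 3 and the 3 muscles alone (0.11).

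Other growth and stress lists were not called. Of 15 genes of serine, nucleotide and one-carbon synthesis 6 were higher (6 adjusted over the list alone; median 0.37, adjusted p = 0.087), including Psat1 of serine synthesis at 3.27 ± 0.45 and the mitochondrial folate enzyme gene Mthfd2 at 2.62 ± 0.36; fry gave this list an adjusted p of 0.0018, and camera 0.047 without tumour 4, 0.027 without tumours 1 and 4, 0.032 without rescaling and 0.038 on tumours 1 to 3 and the 3 muscles alone, in a range of 0.0018 to 0.21 over 23 alternatives. Of 15 hypoxia genes 1 was higher and 4 lower (2 and 4 adjusted over the list alone; median 0.30, adjusted p = 0.91), with 3 higher and 4 lower without tumour 1, and 5 higher and 1 lower without rescaling; leaving out 1 array gave 1 to 3 higher and 2 to 4 lower. Among the lower ones were Egln1 at -2.57 ± 0.41 and Hk2 at -2.18 ± 0.37 (not called without rescaling, adjusted p = 0.069). Of 15 immediate-early genes 3 were higher and 2 lower (the same adjusted over the list alone), with a median of 0.60 (adjusted p = 0.71). Egr1 differed by 1.92 ± 0.42 and Nr4a1 by -3.30 ± 0.43. The Egr1 call was lost without muscle 3 (adjusted p = 0.052) and on tumours 1 to 3 and the 3 muscles alone (0.084). Its range was 0.00016 to 0.084 apart from the rank-sum test. Of 17 imprinted growth genes only Mest was called, at 2.86 ± 0.59 (1 adjusted over the list alone; median -0.14, adjusted p = 0.9). Of 24 receptor tyrosine kinases and ligands Pdgfc was higher at 1.99 ± 0.45 and Igf1 lower at -1.61 ± 0.49 (1 higher and 0 lower adjusted over the list alone; median 0.10, adjusted p = 0.71). Igf1 was not called without any 1 of the muscles (0.088 to 0.13) or without tumour 4 (0.069), tumour 5 (0.061) or tumour 6 (0.05), nor with quantile normalization (0.054), no trend (0.05), the mean of its probe sets (0.12), their median (0.24) or no rescaling (0.33). Of 26 hedgehog, Wnt and Notch genes 3 were higher and 2 lower (the same adjusted over the list alone; median -0.11, adjusted p = 0.99), such as Notch2 at 1.79 ± 0.37, of whose 2 probe sets 1 went the other way (adjusted p = 0.41 with their mean), and Fzd7 at -2.28 ± 0.45. The Fzd7 call was lost without rescaling (0.064) and as the median over its probe sets (0.45, in a range of 0.00058 to 0.45). Without rescaling, the counts were 6 higher and 1 lower for immediate-early, 4 and 0 for imprinted, 7 and 0 for receptor kinase, 5 and 0 for hedgehog, Wnt and Notch, and 5 and 0 for cholesterol genes. Leaving out 1 array gave 0 to 5 higher immediate-early genes, 1 to 3 of the hedgehog, Wnt and Notch list and 2 to 6 of the serine list. Of 13 cholesterol synthesis genes only Sqle was called, at 1.75 ± 0.37 (1 adjusted over the list alone; median 0.31, adjusted p = 0.15), and of 19 proteasome genes only Psmb2, at 1.86 ± 0.40 (1 adjusted over the list alone; median 0.05, adjusted p = 0.85; not called without muscle 3, 0.053). On tumours 1 to 3 and the 3 muscles alone Sqle (0.077), Psmb2 (0.054), Mest (0.054) and Igf1 (0.21) were not called.

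One hypothesis was that tumours with a higher mitotic score have a lower contractile score. Across the 6 tumours Pearson's r between the mean log2 values was -0.488 (exact one-sided permutation p = 0.169, adjusted 0.169 over 2 relations, n = 6), Spearman's rho was -0.543 (exact p = 0.149), and r was -0.594 without the 2 tumours farthest from the median. The direction was the one proposed, but the test did not pass.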
